A study of Mus musculus with 16 samples.

How the data were processed

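RNA sequencing libraries of brown fat, epididymal white fat, inguinal white fat and liver came from C57BL/6 mice given vehicle or sunitinib, with 2 libraries per treatment and tissue. The deposited values were regularized log2 expression per gene and library, made by the authors as 1 table per tissue, as the names of the tables give it. Per the submitters' processing notes, bcl2fastq 2.17.1.14, TopHat2 2.1.1, bedtools and DESeq2 were used with the mouse build mm9, without a stated role for DESeq2. The annotation, the counting settings and the use of strand are not given in the sources used here. Regularized log values are shrunk towards the mean of each gene, most at low counts, so the log2 differences understate the change of genes with few reads. The spread between libraries is shrunk too, so the SEs and p-values of such genes are also affected. They hold no read totals, so the depth per library is unknown and no counting interval is given. Because each tissue was normalized on its own, sunitinib was compared with vehicle only within a table, and differences between tissues are differences of these within-table effects. Shrinkage can differ between tables, so it may be part of such a difference. The reference at hand was another build, so gene symbols are given as in the tables and no coordinates were used. The tables held 21, 25, 21 and 20 symbols that a spreadsheet had turned into dates in brown fat, epididymal white fat, inguinal white fat and liver, and these were not named.

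Groups and replicate numbers were taken from the sample titles. For the sunitinib livers the titles give replicates 3 and 4 while the description labels number the same libraries 1 and 2, and the titles' numbers are used for names. Every deposited column matched 1 sample. No library had the same values as another.

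Genes with a mean of at least 3 over the 4 libraries of a tissue were tested, which kept 13044 of 19664 in brown fat, 15526 of 22972 in epididymal white fat, 14916 of 22103 in inguinal white fat and 12394 of 18566 in liver. Each tissue was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the moderated variance and 2 residual degrees of freedom, to which the fit added 3.28, 2.93, 2.19 and 7.18 prior degrees of freedom in the same order. All tests are two-sided unless stated otherwise. Benjamini-Hochberg adjusted p-values below 0.05 over the genes tested count as passing, and adjusted p-values of single genes come from limma. An exact permutation test with 2 against 2 libraries cannot give a p below 0.333, so none is reported for single genes. Differences between tissues were interaction contrasts in a fit over both tissues with a mean per group, for each of the 6 pairs.

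For groups of genes, 42 lists with 713 unique genes were written down for cell types, metabolic pathways, stress and hormone responses, sunitinib targets with their ligands, and markers of tissues that could be carried over at dissection. Of these genes 16 were in no table. Lists with at least 5 members were tested with camera of limma at a preset correlation of 0.01, with adjustment over 142 tests in the 4 tissues. With an estimated correlation no list passed in any tissue, where the smallest adjusted p was 0.767. That form of camera uses only the 2 residual degrees of freedom, so a pass over 142 tests was hard to reach. The macrophage list of epididymal white fat had an estimated correlation of −0.019, below the preset value. Its camera p still went from 6.23e-15 to 0.0139. A call lost in this way therefore does not by itself show that the genes of a list vary together. The fry test, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes, called 0 lists in each tissue, with 0.0520 the smallest adjusted p. Median, mean and test had the same sign in every called list, and differed in sign in 21 others. Tissue differences of lists were tested in the same way for the lists called in at least 1 tissue, and medians there are over the members tested in both tissues.

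The genes named per tissue were the 10 with the largest log2 difference in each direction among those that passed with both sunitinib libraries on the same side of both vehicle libraries, leaving out predicted and clone names. Where fewer than 5 passed, the 5 of that direction with the smallest p were added as values that did not pass. To these came all sunitinib target kinases, their ligands summarised by the extremes, up to 4 members of each list by p, and the 5 genes with the smallest adjusted p per pair of tissues. Crisp1 and the genes of the closing section outside these rules were chosen after their values were seen. Some genes that these rules name are not reported here. The groups, tests, gene lists, naming rules and most alternatives were fixed before the data were examined.

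The gene fits and the list test at the preset correlation were tested on simulated data with the spread of each tissue, 200 changed genes and 5 data sets per tissue. The simulated genes varied independently of each other, each with a spread estimated from its own 2 residual degrees of freedom. Such estimates are imprecise and real libraries can differ in many genes together. The recovery rates below therefore need not hold in the real data. At a log2 change of 0.5, 1 and 2, brown fat recovered 47.8%, 82.1% and 95.2% over 13044 genes, epididymal white fat 38.5%, 78.2% and 92.4% over 15526 genes, inguinal white fat 0%, 1.19% and 34.5% over 14916 genes and liver 63%, 90.1% and 100% over 12394 genes. Mean false calls per data set were 7, 4.6, 0.2 and 5, and all 5 lists shifted by 0.4 were found in each tissue. In the real data the endothelial list had an estimated correlation of 0.712 in brown fat and 0.882 in epididymal white fat. The simulation does not show how the list test behaves for such lists. For a difference of 2 between the effects in epididymal white fat and liver, 99% of changed genes were recovered over 11831 genes with 6 false calls. Alternatives were no filter, a mean of at least 5, median centring, quantile normalization, a fit without the trend, a robust fit, 1 fit over the 4 tissues, an adjusted p below 0.10, a replicate block and leaving out each library. When a library was left out, the lone library of its group was assumed to vary like the others. The spread within a tissue then came only from the pair left intact. Over genes, differences within the vehicle and sunitinib pairs had SDs of 0.3 and 0.119 in brown fat. They were 0.148 and 0.262 in epididymal white fat, 0.224 and 0.59 in inguinal white fat and 0.122 and 0.123 in liver. Calls lost or gained without a library thus also follow the intact pair's spread. The libraries of both groups did not overlap for 50.2% of tested genes in brown fat, 53.7% in epididymal white fat, 50.4% in inguinal white fat and 37.4% in liver, where chance gives 33.3%.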

Results

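Gene expression was measured by RNA sequencing of total RNA from brown fat, epididymal white fat, inguinal white fat and liver of C57BL/6 mice that were 24 weeks old. The mice had received vehicle or sunitinib (Sutent), an oral inhibitor of receptor tyrosine kinases that include the receptors for vascular endothelial growth factors, platelet-derived growth factors, stem cell factor and colony-stimulating factor. Each tissue had 2 sunitinib and 2 vehicle libraries, which makes 16 libraries in 4 tissues. The series states 8 mice with 4 per treatment. The labels do not say which mouse or pool of mice each library came from, so the p-values measure only the spread between these libraries. The deposited values were regularized log2 expression, from which the number of reads per library cannot be read. The comparisons asked how sunitinib changed expression in each tissue and whether the change differed between tissues. All differences below are log2 sunitinib minus vehicle ± SE, with 2 libraries per group.

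Macrophage genes fell as a list in epididymal white fat after sunitinib, with a median of −0.65 (adjusted p = 0.767 with an estimated correlation). Itgax, which encodes an integrin of macrophages and dendritic cells, fell by 1.53 ± 0.08. Trem2, a lipid-sensing receptor of macrophages, fell by 1.68 ± 0.10 and Tyrobp, the adaptor through which it signals, by 1.11 ± 0.07. Epithelial genes and genes of oxidative phosphorylation rose as lists, with medians of 1.16 and 0.15 (adjusted p = 0.782 with an estimated correlation for each), and the epithelial median was 0.68 without sunitinib replicate 1. Lep, which encodes the adipocyte hormone leptin, fell by 1.01 ± 0.12 (adjusted p = 0.0314) while the 18 adipocyte identity genes had a median of 0.11 and did not pass as a list (adjusted p = 0.524). No gene of this tissue passed without vehicle replicate 1, where the smallest adjusted p was 0.218, or without vehicle replicate 2, where it was 0.257. Lep was also lost without sunitinib replicate 1 (adjusted p = 0.0906) and without sunitinib replicate 2 (adjusted p = 0.0922).

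Of 15526 genes tested with limma in epididymal white fat, 320 fell and 43 rose. At an unadjusted p under 0.05 there were 1849 lower and 1264 higher genes, where 776 in all were expected by chance. The steepest falls were in Ubd, a ubiquitin-like modifier induced by inflammatory cytokines, at −2.87 ± 0.27 (adjusted p = 0.0226), and Gpnmb, a glycoprotein of phagocytes, at −1.99 ± 0.15 (adjusted p = 0.0177). Atp6v0d2, a proton pump subunit of macrophages and osteoclasts, fell by 1.86 ± 0.06, and Adam8, a metalloprotease of myeloid cells, by 1.76 ± 0.09 (adjusted p = 0.0121 for each). Mpeg1, a pore-forming protein of macrophages, stood at −1.65 ± 0.08 and Rgs1, a regulator of G-protein signalling in leukocytes, at −1.54 ± 0.09, both past the test. Tph2, a tryptophan hydroxylase of neurons, fell by 1.86 ± 0.20 and Gpr50, an orphan receptor, by 1.84 ± 0.17. The largest rises were in Gsta4, a glutathione transferase that clears lipid peroxidation products, at 1.25 ± 0.14 (adjusted p = 0.0314), and Cyp2e1, a cytochrome P450, at 1.21 ± 0.13 (adjusted p = 0.0287). Nt5e, an ecto-nucleotidase, rose by 1.19 ± 0.14, Net1, a guanine nucleotide exchange factor, by 1.18 ± 0.07 and Gpx3, a secreted glutathione peroxidase, by 0.92 ± 0.08. Tmprss2, a serine protease, rose by 1.17 ± 0.13, Cd24a, a surface glycoprotein, by 1.14 ± 0.16 and Cldn7, a tight-junction claudin, by 0.99 ± 0.14. Epithelial markers rose as a list in the same libraries. Whether these rises come from epithelial tissue carried over at dissection was not tested. Ank3, a membrane scaffold protein, rose by 1.02 ± 0.13 and Pou3f3, a transcription factor, by 0.93 ± 0.11. With either vehicle library left out these counts were 0 and 0.

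**Figure D1:**
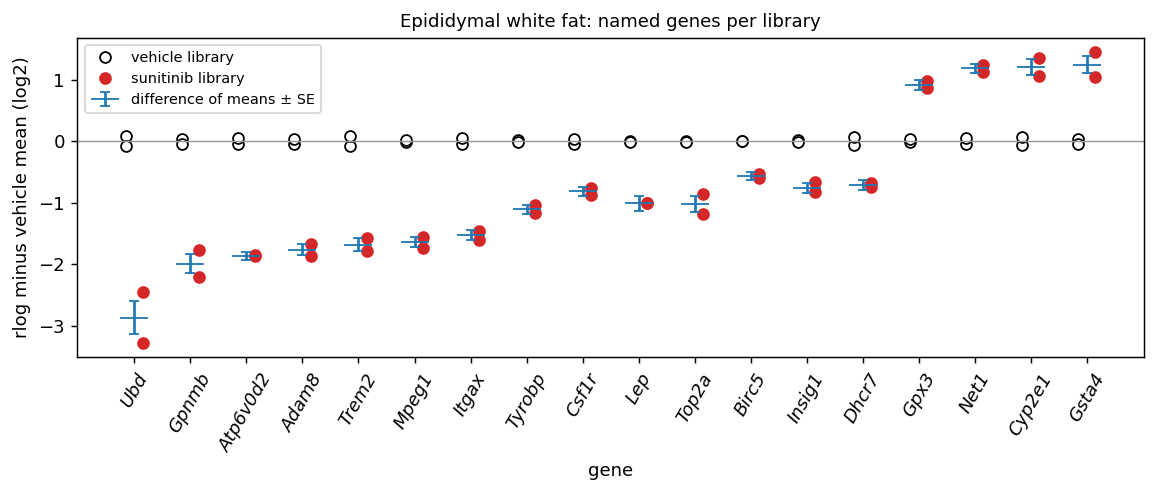
Expression of 18 genes in each epididymal white fat library, as regularized log2 value minus the vehicle mean, with open circles for vehicle, filled circles for sunitinib and a bar for the difference of means ± SE. Ubd lies at −2.87 ± 0.27 and Gsta4 at 1.25 ± 0.14, and in each gene both sunitinib libraries lie on 1 side of both vehicle libraries.

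The macrophage list fell (adjusted p = 4.42e-13, and adjusted p = 0.767 with an estimated correlation). Its 17 measured members had a median of −0.65, and 9 of them fell over all genes tested, against 15 that fell and 1 that rose when adjusted over the list alone. Csf1r, the receptor for macrophage colony-stimulating factor and a sunitinib target, fell by 0.81 ± 0.07 (adjusted p = 0.0212). The proliferation list fell (adjusted p = 1.46e-13, and adjusted p = 0.767 with an estimated correlation), with a median of −0.32, 7 of 24 members past the test over all genes and 21 adjusted over the list alone. Top2a, a DNA topoisomerase, fell by 1.02 ± 0.12, Cdk1, the mitotic kinase, by 0.66 ± 0.08, Tpx2, a spindle protein, by 0.58 ± 0.07 and Birc5, the chromosomal passenger survivin, by 0.56 ± 0.06. Of 23 interferon response genes, Rsad2, an antiviral enzyme, fell by 0.48 ± 0.07 over all genes, and 4 fell adjusted over the list alone. That list had a median of −0.16 (adjusted p = 3.73e-05, and adjusted p = 0.782 with an estimated correlation). The gene calls here were lost without vehicle replicate 1 or vehicle replicate 2, and that of Rsad2 also without sunitinib replicate 1 (adjusted p = 0.0553).

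Extracellular matrix genes fell in epididymal white fat (adjusted p = 4.31e-08, and adjusted p = 0.767 with an estimated correlation). The 24 members had a median of −0.44, of which 2 fell over all genes, the collagens Col6a3 at −0.84 ± 0.11 and Col5a1 at −0.49 ± 0.07, and 15 adjusted over the list alone. Basement membrane genes fell as a list (adjusted p = 7.19e-05, and adjusted p = 0.767 with an estimated correlation) with a median of −0.32 over 10 members. Hspg2, which encodes perlecan, fell by 0.58 ± 0.08 over all genes, and 5 members fell adjusted over the list alone. With quantile normalization the basement membrane median was −0.20. Endothelial genes fell (adjusted p = 2.35e-07, and adjusted p = 0.782 with an estimated correlation), with a median of −0.39 over 26 members, 2 of them past the test over all genes and 9 adjusted over the list alone. Those were Cd93, a glycoprotein of angiogenic endothelium, at −0.94 ± 0.09 and Cd300lg, a capillary receptor, at −0.82 ± 0.09. Gpihbp1, which anchors lipoprotein lipase on capillaries, was at −0.54 ± 0.10 and did not pass. The endothelial median was −0.61 without vehicle replicate 1 and −0.19 without vehicle replicate 2. The 12 angiogenic tip-cell genes fell with a median of −0.18 (adjusted p = 0.00209, and adjusted p = 0.782 with an estimated correlation), with Cxcr4, a chemokine receptor, the only one past the test over all genes at −0.60 ± 0.07 and 4 adjusted over the list alone. Their median was −0.29 without vehicle replicate 1, and −0.12 without vehicle replicate 2, where the list no longer passed (adjusted p = 0.0503). Neither reduced set with 1 vehicle library called any of these genes. Col5a1 and Hspg2 were also lost without sunitinib replicate 1 (adjusted p = 0.0628 and adjusted p = 0.107) and without sunitinib replicate 2 (adjusted p = 0.0632 and adjusted p = 0.0862).

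Cholesterol synthesis genes fell in epididymal white fat (adjusted p = 1.63e-05, and adjusted p = 0.767 with an estimated correlation). The median of 23 members was −0.22, with 5 lower over all genes and 11 adjusted over the list alone. Insig1, a sterol sensor of the endoplasmic reticulum, fell by 0.76 ± 0.08, Dhcr7, the last enzyme of the pathway, by 0.71 ± 0.08 and Sc5d, a sterol desaturase, by 0.45 ± 0.06. Fatty acid and triglyceride synthesis genes rose as a list with a median of 0.12 over 22 members (adjusted p = 0.0166, and adjusted p = 0.782 with an estimated correlation). Acaca, which encodes acetyl-CoA carboxylase, rose by 0.70 ± 0.08 over all genes, and 5 rose adjusted over the list alone. With quantile normalization that median was 0.19. Oxidative phosphorylation genes rose as a list (adjusted p = 1.72e-07, and adjusted p = 0.782 with an estimated correlation) with 42 of 46 members positive and a median of 0.15, while 0 members passed either over all genes in limma or adjusted over the list alone. Ndufb8, of complex I, was at 0.31 ± 0.07 and Sdhb, of complex II, at 0.28 ± 0.07. The single-gene calls were lost when vehicle replicate 1 or vehicle replicate 2 was left out.

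Epithelial and mammary gland markers rose as a list (adjusted p = 1.70e-05, and adjusted p = 0.782 with an estimated correlation). All 12 measured members were positive with a median of 1.16, 0 rose over all genes in limma and 8 rose adjusted over the list alone. Cdh1, the epithelial cadherin, was at 1.44 ± 0.22, and the keratins Krt18 and Krt19 at 1.59 ± 0.38 and 1.55 ± 0.28. Relative to their mean over the tissue, the list stood at −0.62 and −0.28 in the vehicle libraries and at 0.79 and 0.18 in the sunitinib libraries, and its median difference was 0.68 without sunitinib replicate 1. Crisp1, a secreted protein of the epididymal duct, was at 12.7 in that library and at 5.98 in sunitinib replicate 2, with 6.21 and 6.05 in the vehicle libraries.

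The gene counts of epididymal white fat changed when a library was left out, but the spread then came only from the pair left intact. Over genes, differences within the pair had an SD of 0.148 for vehicle and 0.262 for sunitinib. The lost calls therefore do not show that a single vehicle library carried them. Counts were 16 higher and 194 lower with no filter on low values, 104 and 465 with a mean of at least 5, and 108 and 476 with a robust fit. Among named genes, Ank3, Cd24a, Cd300lg, Cldn7, Col5a1, Col6a3, Flt3, Rsad2, Sc5d, Tk1 and Top2a did not pass with no filter, and Acaca, Ank3, Cd24a, Cdk1, Col5a1, Cyp2e1, Gpx3, Lep, Net1, Rsad2, Sc5d, Tk1 and Top2a not in 1 fit over the 4 tissues. Quantile normalization ended the calls of Col6a3, Flt3 and Hspg2, median centring those of Col5a1 and Hspg2, a fit with no trend those of Cd24a, Cldn7 and Flt3, and a robust fit those of Cd24a and Ubd.

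In liver, Hamp, which encodes the iron-regulating hormone hepcidin, rose by 1.13 ± 0.09 after sunitinib (adjusted p = 0.00198). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 1.67 ± 0.11 and Acot3, a peroxisomal acyl-CoA thioesterase, by 1.34 ± 0.09 (adjusted p = 7.97e-04 for each). The endoplasmic reticulum proteins Creld2, Derl3, Hyou1, Sdf2l1 and Manf also rose, with Creld2 at 0.85 ± 0.10, Derl3 at 0.81 ± 0.08, Hyou1 at 0.69 ± 0.08, Sdf2l1 at 0.65 ± 0.08 and Manf at 0.64 ± 0.08. Cholesterol and fatty acid synthesis genes fell as lists, with medians of −0.34 and −0.24 (adjusted p = 0.782 and adjusted p = 0.767 with an estimated correlation). The cholesterol median was −0.13 without sunitinib replicate 3 and −0.52 without sunitinib replicate 4, and the fatty acid median was −0.15 without vehicle replicate 2 and also without sunitinib replicate 3.

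Of 12394 genes tested with limma in liver, 15 rose and 9 fell. At an unadjusted p under 0.05 there were 430 higher and 641 lower genes, against 620 expected in all. Smad9, a signal transducer of bone morphogenetic proteins, rose by 0.79 ± 0.08, and Id1 and Id3, which are transcribed in response to them, rose by 0.67 ± 0.07 and 0.59 ± 0.08. Cyp7b1, an oxysterol hydroxylase of the alternative bile acid pathway, rose by 0.65 ± 0.08. The lower genes were Slc16a5, a monocarboxylate transporter family member, at −0.80 ± 0.11, Thrsp, a regulator of lipogenesis, at −0.73 ± 0.09, Nipal1, a magnesium transporter, at −0.66 ± 0.08 and Tk1, thymidine kinase, at −0.53 ± 0.07. Cyp2a5 at −0.71 ± 0.09 and Cyp2a4 at −0.70 ± 0.09 also fell, but these near-identical paralogs share reads and their values are uncertain. The remaining lower gene was a predicted gene that is not named.

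**Figure D2:**
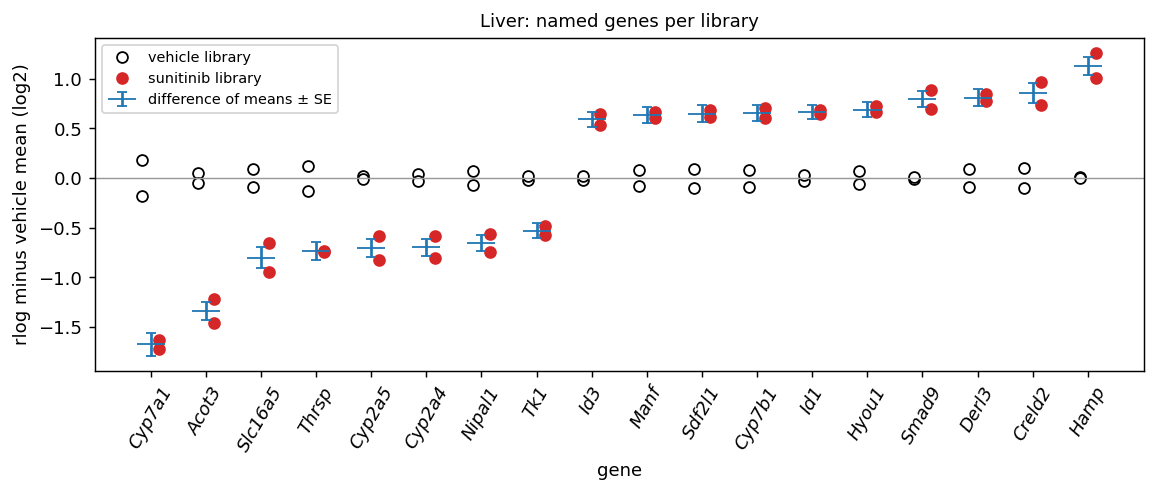
Expression of named liver genes in each library, as regularized log2 value minus the vehicle mean, with open circles for vehicle, filled circles for sunitinib and a bar for the difference of means ± SE. Hamp lies at 1.13 ± 0.09 and Cyp7a1 at −1.67 ± 0.11.

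All 25 cholesterol synthesis genes lay lower in liver, and the list fell (adjusted p = 1.59e-12, and adjusted p = 0.782 with an estimated correlation). Over all genes 0 passed in limma, and 15 fell adjusted over the list alone. Dhcr7 was at −0.61 ± 0.15. The median of −0.34 was −0.13 without sunitinib replicate 3 and −0.52 without sunitinib replicate 4. Fatty acid and triglyceride synthesis genes fell (adjusted p = 7.85e-08, and adjusted p = 0.767 with an estimated correlation) with 20 of 22 negative. Thrsp was the member that passed over all genes, and 8 fell and 1 rose adjusted over the list alone. Scd1, a fatty acid desaturase, was at −0.61 ± 0.14, Acss2, an acetyl-CoA synthetase, at −0.64 ± 0.15 and Srebf1, the lipogenic transcription factor, at −0.39 ± 0.09. The median of −0.24 was −0.15 without vehicle replicate 2 and also −0.15 without sunitinib replicate 3. Bile acid synthesis and transport genes did not pass as a list (adjusted p = 0.608), with Cyp7b1 higher and Cyp7a1 lower among 15 members.

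Stress genes of the endoplasmic reticulum and the integrated stress response rose in liver (adjusted p = 3.56e-05, and adjusted p = 0.767 with an estimated correlation). The 20 members had a median of 0.13, with Sdf2l1 past the test over all genes and 6 adjusted over the list alone. The chaperone Hspa5 was at 0.63 ± 0.10 and the transcription factor Xbp1 at 0.46 ± 0.12. The median of the list was 0.21 with a mean of at least 5. Neutrophil markers rose (adjusted p = 3.39e-05, and adjusted p = 0.782 with an estimated correlation) with a median of 0.19 over 7 members, 3 of them past the test over all genes and 5 adjusted over the list alone. S100a9 rose by 0.51 ± 0.08, S100a8, its partner in calprotectin, by 0.36 ± 0.05 and Ngp, a granule protein, by 0.35 ± 0.04.

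Male-high growth-hormone-dependent genes rose in liver with 15 of 15 positive and a median of 0.26 (adjusted p = 1.18e-10, and adjusted p = 0.767 with an estimated correlation). Cyp7b1 passed over all genes and 10 rose adjusted over the list alone, with the fatty acid elongase Elovl3 at 0.40 ± 0.09. Female-high genes fell with a median of −0.13 over 10 members (adjusted p = 5.31e-04, and adjusted p = 0.782 with an estimated correlation), and −0.22 with a mean of at least 5. Acot3 and Cyp2a4 were the 2 that fell over all genes, and adjusted over the list alone 4 fell and 2 rose. Xenobiotic metabolism genes fell with a median of −0.09 over 21 members (adjusted p = 0.00150, and adjusted p = 0.782 with an estimated correlation). Cyp2a5 passed over all genes, and adjusted over the list alone 4 fell and 2 rose. Their median was −0.06 without vehicle replicate 2 (adjusted p = 0.0533) and −0.18 without sunitinib replicate 4.

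Endothelial genes fell in liver with a median of −0.12 over 25 members (adjusted p = 2.27e-05, and adjusted p = 0.782 with an estimated correlation), 0 past the test over all genes in limma and 2 adjusted over the list alone. Ptprb, an endothelial phosphatase, was at −0.49 ± 0.11 and Cd300lg at −0.37 ± 0.07, and the median was −0.05 without vehicle replicate 2. Oxidative phosphorylation genes fell with 39 of 46 negative and a median of −0.06 (adjusted p = 6.25e-04, and adjusted p = 0.782 with an estimated correlation), with 0 members past the test over all genes or adjusted over the list alone. That call was lost without vehicle replicate 1 (median −0.03, adjusted p = 0.221) and without sunitinib replicate 4 (median −0.03, adjusted p = 0.219). Fatty acid oxidation genes had a median of −0.07 over 27 members and fell as a list (adjusted p = 0.00327, and adjusted p = 0.876 with an estimated correlation), again with 0 members past either adjustment. That call was lost without vehicle replicate 1 (median −0.08, adjusted p = 0.0647) and without sunitinib replicate 3 (median −0.01, adjusted p = 0.490), and the median was −0.17 without sunitinib replicate 4.

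Circadian clock genes fell in liver with a median of −0.12 over 15 members (adjusted p = 0.0359, and adjusted p = 0.782 with an estimated correlation), with 0 past the test over all genes and 2 adjusted over the list alone. The period gene Per3 was at −0.45 ± 0.08. The clock call was lost without vehicle replicate 1 (median −0.08, adjusted p = 0.196) and without sunitinib replicate 4 (median −0.09, adjusted p = 0.246), and the median was −0.07 without vehicle replicate 2. Macrophage genes fell by the list test in liver with a median of −0.07 over 16 members (adjusted p = 0.0359, and adjusted p = 0.900 with an estimated correlation) and 0 members past either adjustment. The macrophage call was lost with a mean of at least 5 (adjusted p = 0.113), without vehicle replicate 2 (median 0.003, adjusted p = 0.921) and without sunitinib replicate 4 (median −0.001, adjusted p = 0.966). The median was −0.16 without vehicle replicate 1 and −0.14 without sunitinib replicate 3.

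The liver gene counts were 48 higher and 119 lower without vehicle replicate 1, 21 and 29 without vehicle replicate 2, 42 and 68 without sunitinib replicate 3, and 175 and 279 without sunitinib replicate 4. Without an intensity trend in the variance 1 gene rose and 2 fell, which were Hamp, Cyp7a1 and Acot3, and in 1 fit over the 4 tissues 0 genes passed in either direction. With a replicate block by the numbers of the description labels 287 rose and 470 fell. The labels do not say whether libraries of the same number share an animal. S100a8, S100a9 and Tk1 did not pass with no filter, S100a9 not with a mean of at least 5, and S100a8, S100a9, Slc16a5 and Tk1 not with quantile normalization.

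In brown fat, endothelial genes rose as a list after sunitinib, with 26 of 26 members positive and a median of 0.36 (adjusted p = 0.782 with an estimated correlation). The median was 0.23 without vehicle replicate 2, which was the lowest library for these genes, at −0.35 relative to the tissue mean, and stood apart with skeletal muscle markers at 2.03 and 22.6 on the leading principal component. The endothelial receptor Tie1 was at 0.59 ± 0.10, the transcription factors Sox18 and Sox7 at 0.54 ± 0.10 and 0.52 ± 0.10 and Aplnr, the apelin receptor, at 0.38 ± 0.07. Oxidative phosphorylation genes rose as a list with a median of 0.19, and fatty acid and triglyceride synthesis genes fell with a median of −0.20 (adjusted p = 0.782 with an estimated correlation for each). The thermogenic genes did not pass as a list, with a median of 0.03 over 17 members (adjusted p = 0.524).

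No single gene passed in brown fat. Of 13044 genes tested with limma, 0 rose and 0 fell, with 0.228 the smallest adjusted p, while 1191 higher and 910 lower genes had an unadjusted p under 0.05 against 652 expected in all. Of the alternatives tried on all 4 libraries, only the fit over the 4 tissues gave a call, with 0 higher and 1 lower gene. The smallest p-values on the higher side belonged to Mt1, a metallothionein, at 0.62 ± 0.07, Vwa1, a matrix protein, at 0.49 ± 0.06, Glt1d1 at 0.66 ± 0.09, Crip2 at 0.56 ± 0.07 and Maff at 0.46 ± 0.06. On the lower side they belonged to Npr3, the clearance receptor for natriuretic peptides, at −1.06 ± 0.14, Pank3, a pantothenate kinase, at −0.72 ± 0.10, Ank at −0.59 ± 0.07, mt-Nd5, a mitochondrially encoded subunit of complex I, at −0.45 ± 0.06 and Slc15a5 at −0.37 ± 0.05. None of these passed (adjusted p = 0.229 for each).

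The endothelial list in brown fat (adjusted p = 3.21e-11, and adjusted p = 0.782 with an estimated correlation) had 16 members higher adjusted over the list alone and 0 over all genes in limma. Its median was 0.23 without vehicle replicate 2. Angiogenic tip-cell genes rose with a median of 0.17 over 11 members (adjusted p = 0.00235, and adjusted p = 0.767 with an estimated correlation), 0 over all genes, and 6 higher and 1 lower adjusted over the list alone. Dll4, a Notch ligand of tip cells, was at 0.53 ± 0.08 and Pdgfb, which recruits pericytes, at 0.55 ± 0.09, and with a mean of at least 5 the median was 0.37. Basement membrane genes rose with a median of 0.29 over 10 members (adjusted p = 0.0130, and adjusted p = 0.782 with an estimated correlation), 0 over all genes and 1 adjusted over the list alone, and without sunitinib replicate 2 the call was lost (median 0.19, adjusted p = 0.245). Nid2, a nidogen that is also in the tip-cell list, was at 0.47 ± 0.08.

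Mitochondrial genes encoded in the nucleus rose as lists in brown fat. Oxidative phosphorylation (adjusted p = 1.02e-09, and adjusted p = 0.782 with an estimated correlation) had 40 of 46 members positive, 0 past the test over all genes and 16 adjusted over the list alone, with Cox5b of complex IV at 0.38 ± 0.07 and Ndufb10 of complex I at 0.33 ± 0.06. Mitochondrial ribosomal genes rose with 28 of 32 positive and a median of 0.13 (adjusted p = 6.91e-07, and adjusted p = 0.767 with an estimated correlation), 0 past the test over all genes and 2 adjusted over the list alone. Fatty acid and triglyceride synthesis genes fell (adjusted p = 1.28e-04, and adjusted p = 0.782 with an estimated correlation) with 18 of 22 negative, 0 past the test over all genes and 6 adjusted over the list alone. Acly, which makes cytosolic acetyl-CoA, was at −0.87 ± 0.14, Me1, malic enzyme, at −0.71 ± 0.13 and Pnpla3, a lipid droplet acyltransferase or lipase, at −0.67 ± 0.12.

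Macrophage genes fell as a list in brown fat with a median of −0.11 over 16 members (adjusted p = 0.00464, and adjusted p = 0.782 with an estimated correlation), 0 past the test over all genes and 2 adjusted over the list alone, with Mpeg1 at −0.40 ± 0.07 and Ccr2 at −0.35 ± 0.06. The macrophage median was −0.22 without vehicle replicate 1, and without vehicle replicate 2 the call was lost (median −0.02, adjusted p = 0.153). Thyroid hormone response genes fell with a median of −0.11 over 12 members (adjusted p = 0.00991, and adjusted p = 0.782 with an estimated correlation), 0 past the test over all genes and 1 adjusted over the list alone. Their median was −0.19 with a mean of at least 5, and without vehicle replicate 1 the call was lost (median −0.08, adjusted p = 0.105). Cholesterol synthesis genes fell with a median of −0.12 over 23 members (adjusted p = 0.0359, and adjusted p = 0.900 with an estimated correlation), 0 past the test over all genes, and 4 lower and 2 higher adjusted over the list alone. That call was lost without vehicle replicate 1 (median −0.06, adjusted p = 0.505) and without sunitinib replicate 1 (median −0.07, adjusted p = 0.307). Hepatocyte genes, a marker list of another tissue, fell with a median of −0.11 over 16 members (adjusted p = 0.0440, and adjusted p = 0.900 with an estimated correlation) and 0 past either adjustment. The hepatocyte call was lost with a mean of at least 5 (adjusted p = 0.0712), without vehicle replicate 2 (median −0.01, adjusted p = 0.774) and without sunitinib replicate 2 (median −0.10, adjusted p = 0.306), and the median was −0.26 without vehicle replicate 1. Skeletal muscle genes did not pass in brown fat (adjusted p = 0.513) but set the libraries apart, at −1.58 and 2.03 in the vehicle libraries and 0.20 and −0.56 in the sunitinib libraries.

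The gene counts of brown fat were 472 higher and 820 lower without vehicle replicate 1 and 369 and 287 without vehicle replicate 2. They were 0 and 0 without either sunitinib library, and the lone library of a group was then assumed to vary like the others.

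In inguinal white fat, markers of skeletal muscle fell and markers of B lymphocytes rose as lists after sunitinib, with medians of −2.99 and 2.97 (adjusted p = 0.782 with an estimated correlation for each). Without sunitinib replicate 2 these medians were −1.14 and 1.39, and without sunitinib replicate 1 they were −4.86 and 4.52. Extracellular matrix genes fell as a list with a median of −0.59 and macrophage genes with −0.41 (adjusted p = 0.782 with an estimated correlation for each), and cholesterol synthesis genes with −0.48 (adjusted p = 0.767 with an estimated correlation). The matrix protein periostin, Postn, was at −0.79 ± 0.09 and the sterol sensor Insig1 at −0.88 ± 0.10. Sunitinib replicate 2 stood apart from the other libraries, at 57.8 on the leading principal component, which held 77.2% of the variance, against −29.0, −22.5 and −6.37. The libraries may differ in muscle or lymph node carried over at dissection, which these data cannot tell apart from an effect of sunitinib. Whether such differences in composition also moved the other lists of this tissue was not tested.

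No single gene passed in inguinal white fat. Of 14916 genes tested with limma, 0 rose and 0 fell, with 0.200 the smallest adjusted p, while 578 higher and 1313 lower genes had an unadjusted p under 0.05 against 746 expected in all. The genes with the smallest p-values on the lower side are expressed in skeletal muscle. They were Csrp3, a muscle LIM protein, at −3.19 ± 0.14, Mybpc1, a myosin-binding protein of slow fibres, at −4.43 ± 0.31, Ankrd2 at −2.70 ± 0.17, Smtnl1 at −2.25 ± 0.14 and Fabp3-ps1, a pseudogene of the heart fatty acid binding protein, at −3.00 ± 0.22, where reads shared with Fabp3 leave the value uncertain. On the higher side they were Hs3st3b1 at 1.39 ± 0.16, Peli1 at 0.93 ± 0.12, Irf4, a transcription factor of lymphocytes and adipocytes, at 1.85 ± 0.29, Dennd2d at 1.55 ± 0.25 and AI838599 at 0.79 ± 0.11. Their adjusted p-values ran from 0.200 to 0.310.

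The skeletal muscle list (adjusted p = 3.17e-06, and adjusted p = 0.782 with an estimated correlation) had 16 of 16 members negative, 0 past the test over all genes and 1 adjusted over the list alone, with Myh7, a slow myosin, at −2.75 ± 0.34. Per library it stood at 2.12 and 0.74 in the vehicle libraries and at 0.28 and −3.30 in the sunitinib libraries. Its median difference was −4.86 without sunitinib replicate 1 and −1.14 without sunitinib replicate 2. The B lymphocyte list (adjusted p = 1.32e-04, and adjusted p = 0.782 with an estimated correlation) had 9 of 9 members positive and 0 past either adjustment, with the B cell receptor chain Cd79a at 3.19 ± 1.15. Per library it stood at −1.91 and −1.05 in the vehicle libraries and at −0.05 and 3.01 in the sunitinib libraries, and its median difference was 4.52 without sunitinib replicate 1 and 1.39 without sunitinib replicate 2. T and NK lymphocyte genes rose with a median of 1.98 over 14 members (adjusted p = 0.00479, and adjusted p = 0.900 with an estimated correlation), 0 past either adjustment. That median was 3.68 without sunitinib replicate 1, and the call was lost without sunitinib replicate 2 (median 0.25, adjusted p = 0.0694). Neutrophil genes rose with a median of 0.71 over 9 members (adjusted p = 0.00250, and adjusted p = 0.782 with an estimated correlation), 0 past either adjustment. The neutrophil median was 1.24 without sunitinib replicate 1, and the call was lost with a mean of at least 5 (adjusted p = 0.105).

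**Figure D3:**
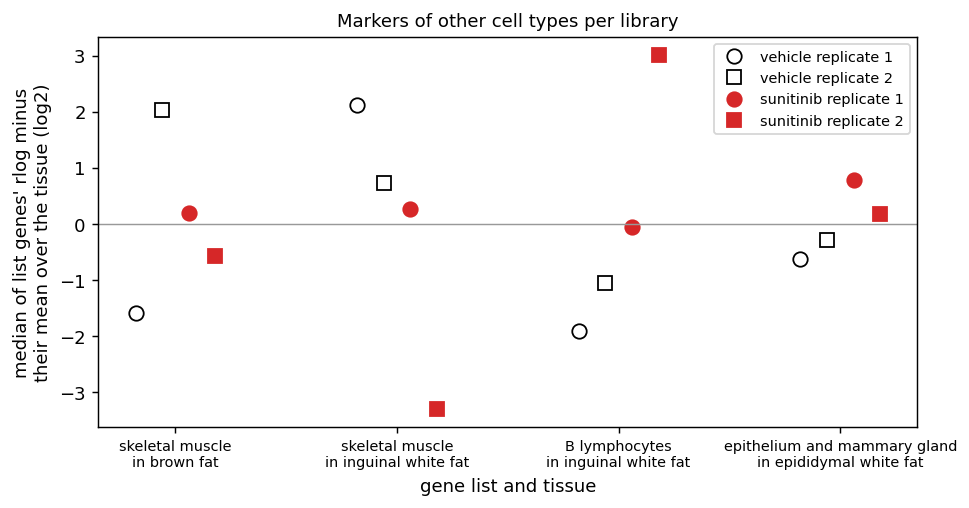
Median of each marker list per library, as regularized log2 value minus the mean of each gene over the tissue, for vehicle (open) and sunitinib (filled) replicates 1 (circles) and 2 (squares). Sunitinib replicate 2 of inguinal white fat lies at −3.30 for skeletal muscle and 3.01 for B lymphocytes, and vehicle replicate 2 of brown fat at 2.03 for skeletal muscle.

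Extracellular matrix genes fell as a list in inguinal white fat (adjusted p = 3.28e-09, and adjusted p = 0.782 with an estimated correlation), with 22 of 24 negative, 0 past the test over all genes and 8 adjusted over the list alone. Fibronectin, Fn1, was at −0.75 ± 0.14 and fibrillin, Fbn1, at −0.90 ± 0.17. Basement membrane genes fell with a median of −0.54 over 10 members (adjusted p = 4.22e-05, and adjusted p = 0.782 with an estimated correlation), 0 over all genes and 5 adjusted over the list alone. Endothelial genes fell (adjusted p = 3.78e-06, and adjusted p = 0.782 with an estimated correlation), with 25 of 26 negative, 0 past the test over all genes and 6 adjusted over the list alone. Aplnr was at −1.41 ± 0.14, Cd93 at −0.75 ± 0.12 and Tie1 at −0.54 ± 0.10, and the median of −0.33 was −0.16 without sunitinib replicate 2. Angiogenic tip-cell genes fell with a median of −0.45 over 12 members (adjusted p = 1.93e-04, and adjusted p = 0.767 with an estimated correlation), 0 over all genes and 7 adjusted over the list alone, and the call was lost without sunitinib replicate 1 (median −0.39, adjusted p = 0.0505). Apln, the ligand of Aplnr, was at −0.88 ± 0.22. Pericyte and smooth muscle genes fell with 14 of 14 negative and a median of −0.31 (adjusted p = 7.97e-05, and adjusted p = 0.767 with an estimated correlation), 0 over all genes and 1 adjusted over the list alone, with the pericyte gene Rgs5 at −0.80 ± 0.09.

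Cholesterol synthesis genes fell in inguinal white fat (adjusted p = 4.41e-06, and adjusted p = 0.767 with an estimated correlation), with 18 of 23 negative, 0 past the test over all genes and 8 adjusted over the list alone. Hmgcs1, an early enzyme of the pathway, was at −0.85 ± 0.13. Macrophage genes fell (adjusted p = 4.63e-05, and adjusted p = 0.782 with an estimated correlation), with 16 of 17 negative, 0 past the test over all genes and 5 adjusted over the list alone. The mannose receptor Mrc1 was at −0.75 ± 0.13, the scavenger receptor Cd163 at −1.10 ± 0.24 and the complement gene C1qb at −0.43 ± 0.09.

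The gene counts of inguinal white fat were 2384 higher and 1719 lower without sunitinib replicate 1, 272 and 461 without sunitinib replicate 2, and 0 and 0 without either vehicle library. A fit over the 4 tissues gave 1195 higher and 1230 lower genes, but it took 1 variance per gene over all tissues. Over genes, the difference within the inguinal sunitinib pair had an SD of 0.59. For the sunitinib pairs of brown fat, epididymal white fat and liver it was 0.119, 0.262 and 0.123. Those counts therefore judge inguinal libraries against the smaller spread of other tissues.

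**Figure D4:**
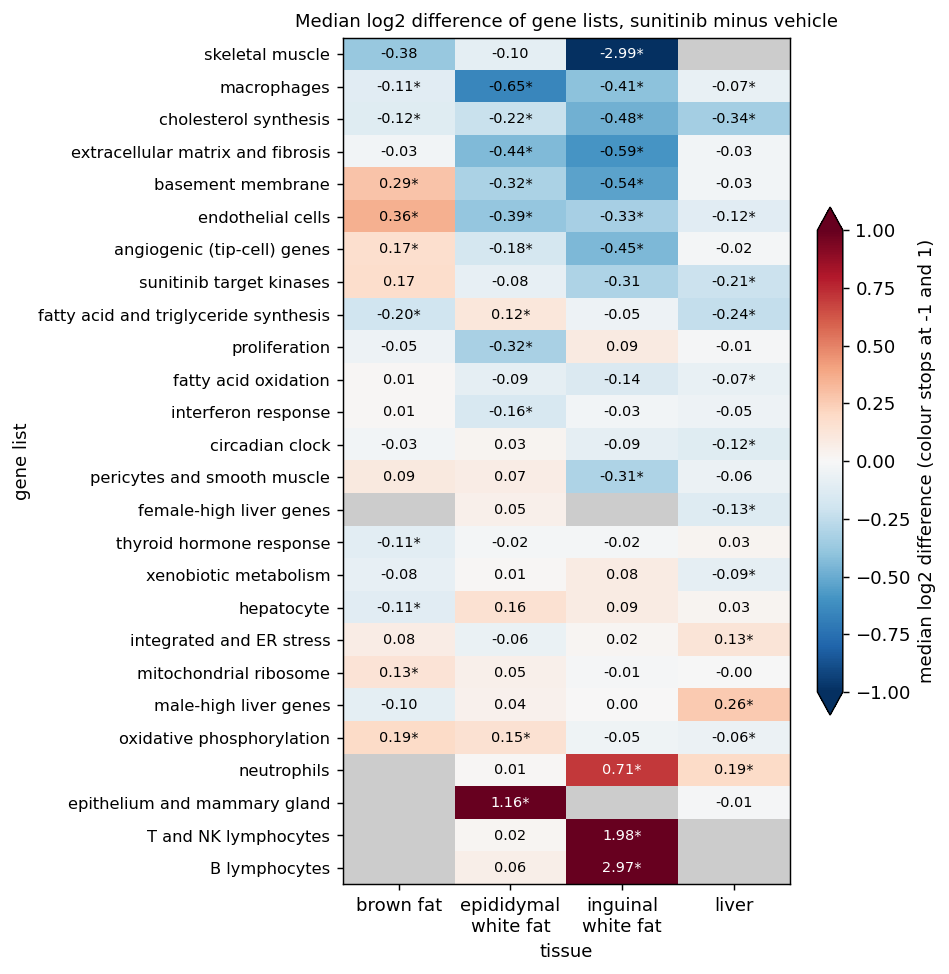
Median log2 difference, sunitinib minus vehicle, of the gene lists that passed in at least 1 tissue, with colour from −1 to 1, an asterisk for lists past the test and grey where fewer than 5 members were measured. The endothelial list has a median of 0.36 in brown fat, −0.39 in epididymal white fat, −0.33 in inguinal white fat and −0.12 in liver.

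The receptor tyrosine kinases that sunitinib inhibits were measured in each tissue. In epididymal white fat Csf1r fell by 0.81 ± 0.07 and Flt3 by 0.35 ± 0.05 (adjusted p = 0.0491), while Pdgfrb at −0.54 ± 0.14, Flt1 at −0.39 ± 0.10, Kdr at −0.08 ± 0.17, Ret at −0.06 ± 0.12, Pdgfra at 0.02 ± 0.07, Kit at 0.10 ± 0.17 and Flt4 at 0.18 ± 0.18 did not pass. Both calls were lost without vehicle replicate 1 or vehicle replicate 2. Adjusted over the list alone 4 of its 9 members fell, and the list did not pass (adjusted p = 0.0670). In liver the 7 measured kinases were all negative and fell as a list (adjusted p = 2.73e-04, and adjusted p = 0.782 with an estimated correlation), with 0 past the test over all genes in limma and 1 adjusted over the list alone. Kdr was at −0.31 ± 0.12, Flt1 at −0.25 ± 0.09, Flt4 at −0.24 ± 0.09, Kit at −0.21 ± 0.06, Csf1r at −0.14 ± 0.12, Pdgfra at −0.11 ± 0.07 and Pdgfrb at −0.08 ± 0.07. The liver median of −0.21 was −0.12 without vehicle replicate 2. In brown fat none passed, with the vascular receptors Kdr, Flt1 and Flt4 at 0.49 ± 0.13, 0.49 ± 0.15 and 0.40 ± 0.11, Pdgfrb at 0.37 ± 0.09, Ret at −0.02 ± 0.05, Pdgfra at −0.04 ± 0.09, Kit at −0.10 ± 0.07 and Csf1r at −0.39 ± 0.12 (list adjusted p = 0.368), though adjusted over the list alone 4 were higher and 1 lower. In inguinal white fat none passed, with Ret at −1.01 ± 0.16, Kit at −0.55 ± 0.23, Csf1r at −0.41 ± 0.17, Flt1 at −0.31 ± 0.24, Pdgfrb at −0.31 ± 0.09, Pdgfra at −0.25 ± 0.15, Kdr at −0.01 ± 0.11, Flt4 at 0.34 ± 0.25 and Flt3 at 0.60 ± 0.80 (list adjusted p = 0.0882), though adjusted over the list alone 1 was lower.

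No ligand of these kinases passed over all genes in any tissue, and adjusted over the list alone 1 did, in brown fat. Values ran from −0.18 ± 0.07 for Pdgfc to 0.55 ± 0.09 for Pdgfb in brown fat, from −0.32 ± 0.12 for Pdgfb to 0.38 ± 0.10 for Vegfa in epididymal white fat, from −0.53 ± 0.16 for Pgf to 0.96 ± 0.54 for Flt3l in inguinal white fat and from −0.19 ± 0.07 for Csf1 to 0.05 ± 0.06 for Vegfc in liver. The ligand list had adjusted p-values of 0.628, 0.524, 0.173 and 0.376 in these tissues.

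Macrophage genes fell further in epididymal white fat than in brown fat or liver when the difference of the effects was tested. Shrinkage can differ between the tables and is strongest for genes with few reads. Mpeg1 had a mean of 10.99 in epididymal white fat, 6.6 in brown fat and 8.73 in liver, levels from separately normalized tables. A smaller fall in brown fat or liver therefore cannot be told apart from stronger shrinkage there. Over the members tested in both tissues, the list medians differed by 0.52 for brown minus epididymal white fat (adjusted p = 5.72e-08, and adjusted p = 0.318 with an estimated correlation) and by −0.56 for epididymal white fat minus liver (adjusted p = 5.72e-08, and adjusted p = 0.390 with an estimated correlation). Adam8 changed by 1.67 ± 0.12 and Itgax by 1.50 ± 0.10 more in the positive direction in brown fat than in epididymal white fat (adjusted p = 0.00254 for each), as did the myosin Myo1e by 1.24 ± 0.08, the transporter Slc37a2 by 1.49 ± 0.10 and Wdfy4, a protein of antigen presentation, by 1.07 ± 0.08. Epididymal white fat minus liver gave −1.69 ± 0.12 for Trem2, −1.43 ± 0.10 for Slc37a2, −1.31 ± 0.10 for the myeloid receptor Clec12a, −1.61 ± 0.12 for Atp6v0d2 and −1.54 ± 0.10 for the matrix protein Hmcn2 (adjusted p = 7.94e-04 for each). In all, the effect differed for 461 of 12661 genes between brown and epididymal white fat, 379 of them with a positive difference, and for 467 of 11831 genes between epididymal white fat and liver, 134 with a positive and 333 with a negative difference.

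Between brown and inguinal white fat the effect differed for 4 genes, which were Fabp3-ps1 at 3.19 ± 0.23, Fabp3 at 2.63 ± 0.22, Aplnr at 1.79 ± 0.15 and the muscle gene Mss51 at 2.79 ± 0.24 (adjusted p = 0.0453 for each). All 4 calls were lost without any single brown fat library and without inguinal vehicle replicate 1 or 2, where 0.0750 was the smallest of their adjusted p-values, and 3 of them, all but Mss51, with quantile normalization. Between inguinal white fat and liver it differed for 5 genes, which were the muscle genes Csrp3 at −2.81 ± 0.15, Ankrd2 at −2.63 ± 0.16, Mss51 at −2.82 ± 0.23 and Lmod2 at −3.43 ± 0.28, and Hmcn2 at −1.43 ± 0.13. Only Ankrd2 of these passed without inguinal vehicle replicate 1 or 2 and only Csrp3 without liver vehicle replicate 1, while none did without liver vehicle replicate 2 or sunitinib replicate 3 or 4, where 0.0608 was the smallest of their adjusted p-values. Quantile normalization ended the calls of Lmod2 (adjusted p = 0.0547) and Hmcn2 (adjusted p = 0.0798). With a replicate block 0 genes differed for either pair. With a mean of at least 5 there were 3 between brown and inguinal white fat and 1 between inguinal white fat and liver. Skeletal muscle markers differed between the inguinal libraries as given above. Between brown fat and liver 0 genes differed in limma, with 1610 at an unadjusted p under 0.05 against 560 expected and 23 by separate fits. Between epididymal and inguinal white fat 0 genes differed, with 1443 at an unadjusted p under 0.05 against 718 expected and 1 by separate fits.

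Endothelial genes had a higher effect in brown fat than in each other tissue, by difference of the list medians 0.75 against epididymal white fat (adjusted p = 4.47e-11, and adjusted p = 0.504 with an estimated correlation), 0.69 against inguinal white fat (adjusted p = 1.21e-12, and adjusted p = 0.390 with an estimated correlation) and 0.46 against liver (adjusted p = 2.93e-14, and adjusted p = 0.390 with an estimated correlation). Without brown fat vehicle replicate 2, which had skeletal muscle markers at 2.03 and endothelial genes at −0.35 relative to the tissue mean, the brown fat median was 0.23 and these differences were 0.62, 0.56 and 0.34. Without epididymal vehicle replicate 2 the epididymal median was −0.19 and the difference 0.55. Of 129 list differences tested, 72 passed and 0 did so with an estimated correlation, where 0.318 was the smallest adjusted p. In 11 of them the list passed in opposite directions in the 2 tissues, so the difference was largely set by those calls.

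The gene counts of these differences moved when single libraries were left out, which also took the pair of that library out of the spread. Between brown and epididymal white fat they were 714 without brown fat vehicle replicate 1, 305 without vehicle replicate 2, 80 and 120 without sunitinib replicates 1 and 2, and 260 and 127 without epididymal vehicle replicates 1 and 2. Between epididymal white fat and liver they were 294 without epididymal vehicle replicate 2, 711 without epididymal sunitinib replicate 1, and 159, 201, 157 and 267 without liver vehicle replicates 1 and 2 and sunitinib replicates 3 and 4. Without inguinal sunitinib replicates 1 and 2 they were 2424 and 410 against brown fat, 3059 and 17 against epididymal white fat, and 3046 and 856 against liver, and without any other library 0 or 1 against brown fat, 0 against epididymal white fat and 0 or 1 against liver. Between brown fat and liver they were 325 and 35 without brown fat vehicle replicates 1 and 2, 3 without liver sunitinib replicate 4 and 0 otherwise.

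Tk1 was the only gene that fell in both epididymal white fat and liver. Brown fat and inguinal white fat had no genes past the test, so pairs with either of them could share none. Its epididymal call was lost without vehicle replicate 1 (adjusted p = 0.288), vehicle replicate 2 (adjusted p = 0.333) or sunitinib replicate 1 (adjusted p = 0.0528). For this pair 0.132 shared lower genes were expected for independent lists, and Fisher's exact test gave a one-sided p = 0.125. Across genes, log2 differences had a Pearson r of 0.379 (Spearman rho 0.259) between brown and inguinal white fat, 0.177 (0.268) between epididymal and inguinal white fat, 0.0910 (0.106) between inguinal white fat and liver, 0.0680 (0.0575) between brown fat and liver, 0.0187 (0.0115) between epididymal white fat and liver and −0.0107 (−0.00207) between brown and epididymal white fat. Genes are not independent replicates, so these correlations carry no p-value.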

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

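Except for the test of resident macrophage markers, the tests of explanations in this part were chosen only after the result was seen.

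Macrophage genes were lower in epididymal white fat of sunitinib mice, with a list median of −0.65. Dilution by epithelial tissue would lower adipocyte genes alike, but the lower quartile of the adipocyte identity list was −0.10, and a shift of library scaling is argued against by quantile normalization, which left the macrophage median at −0.61. A single divergent library is argued against by the list's median, which was −0.57 at its nearest to 0 without any 1 library. Equal loss of all macrophages was tested with 10 resident tissue macrophage markers, 2 of them also in the macrophage list. Their median was −0.045 with quartiles of −0.34 and 0.10, but they moved in both directions. Folr2 fell by 0.54 ± 0.06 (adjusted p = 0.0297 in limma, lost without vehicle replicate 1 or 2). Cd163, Mrc1, Pf4, Ccl8 and F13a1 were at −0.44, −0.38, −0.23, −0.063 and −0.026. Timd4, Gas6, Cbr2 and Lyve1 were at 0.066, 0.11, 0.20 and 0.43. With markers this mixed, the median cannot decide whether resident macrophages were lost as much as others. A loss or a changed state of some or all macrophages after sunitinib may remain as a hypothesis that was not tested. These data do not separate fewer cells from lower expression per cell.

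Epithelial genes were higher in epididymal white fat of sunitinib mice, with a list median of 1.16. Crisp1, an abundant transcript of the epididymal duct, lay 6.45 above the higher vehicle library in sunitinib replicate 1, so duct tissue carried over at dissection is a candidate source there. In sunitinib replicate 2 Crisp1 lay at −0.23 from that library, which argues against Crisp1-expressing duct in it. Adam7, another gene of the duct, was 5.32 there and 5.06 in sunitinib replicate 1, against 4.73 and 4.76 in the vehicle libraries. The other measured genes of the epididymis list, Spink11, Defb2, Lcn5 and Cst8, lay below the filter of 3. In sunitinib replicate 2 they were 2.74, 2.30, 1.75 and 2.60, against 2.74, 2.30, 1.75 and 2.58 in vehicle replicate 1. In sunitinib replicate 1 they were 2.96, 2.44, 1.85 and 2.74, so they went with Crisp1 rather than Adam7. Fewer macrophages would raise every other cell type alike, which the upper quartile of the adipocyte identity list, 0.26, argues against. Duct or other epithelium without Crisp1 stays open for both sunitinib libraries, where Pax8 was 7.96 and 7.81 and Foxj1 7.57 and 9.42, against 6.25 and 6.87 for Pax8 and 6.41 and 7.72 for Foxj1 in the vehicle libraries, and so does an effect of sunitinib, which was not tested.

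Sunitinib replicate 2 of inguinal white fat stood apart, with B lymphocyte markers at 3.01 and skeletal muscle markers at −3.30 relative to the tissue mean. Of 6 genes of lymph node stroma and high endothelial venules, without Cr2 and Fcer2a, which B lymphocytes make, 5 were highest in this library, all but Enpp2, which adipocytes also make. Glycam1 of the venules was 8.88 there, 7.10 in sunitinib replicate 1 and 4.44 and 4.41 in the vehicle libraries, so lymph node tissue may be part of the difference but cannot be told apart from other sources with 1 library. A swap with an epididymal white fat library is argued against by the 46 genes at 6 or more in every epididymal library and below a mean of 3 over the other inguinal libraries, which in this library lay at a median of 0.014 from those, with quartiles of −0.058 and 0.090. An effect of sunitinib on this library alone was not tested, and neither was uneven carry-over of skeletal muscle at dissection.

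Effects that differed between tissues by a test of the difference itself, with the list called in opposite directions, were as follows as differences of list medians. These lists were picked by their opposite calls on the same libraries. All 11 such differences passed, so the test adds little to those calls. None of these list differences passed with an estimated correlation, where 0.318 was the smallest adjusted p. Endothelial genes differed by 0.46 for brown fat minus liver, 0.69 for brown minus inguinal white fat and 0.75 for brown minus epididymal white fat. Oxidative phosphorylation genes differed by 0.25 for brown fat minus liver and 0.21 for epididymal white fat minus liver. Basement membrane genes differed by 0.82 for brown minus inguinal white fat and 0.61 for brown minus epididymal white fat. Angiogenic tip-cell genes differed by 0.66 and 0.38 for the same pairs, and the latter was 0.58 with a mean of at least 5. Fatty acid and triglyceride synthesis genes differed by −0.31 for brown minus epididymal white fat and 0.35 for epididymal white fat minus liver. The tests of single genes found a difference for 461 genes between brown and epididymal white fat (80 to 714 without 1 library), 4 between brown and inguinal white fat (0 to 2424), 467 between epididymal white fat and liver (157 to 711) and 5 between inguinal white fat and liver (0 to 3046), with the values per library given beside the comparison.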

How the results depend on the processing

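The crossed pairing was the only test of this part chosen after the result was seen. With 2 libraries per group, counts of single genes changed more than the direction of their values. Leaving out either vehicle library ended every gene call in epididymal white fat. The 363 called genes kept their sign without each library in turn, but this was fixed in advance. In each of them both sunitinib libraries lay on the same side of both vehicle libraries, so no single omission could turn the sign. In liver the genes called with all libraries were called again without each library, except 1 without vehicle replicate 2. Without 1 library, the spread of a tissue came only from the pair left intact, so such changes cannot be laid to the omitted library alone. Other causes of the changes below were not tested. What depth limits is unknown, since the values hold no read totals. Count-based tests with other size factors and another pseudocount were not run, because the deposited values are log2 values. Of the alternative values of single genes and tissue differences, 1933 kept their direction and their side of the threshold, 240 no longer passed, 177 passed newly and 16 turned direction. Of those of called lists, 336 stayed, 22 no longer passed and 1 turned direction. This tally leaves out camera with an estimated correlation and fry, each of which ended every list call.

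Gene counts higher and lower were 43 and 320 in epididymal white fat, 16 and 194 with no filter, 104 and 465 with a mean of at least 5, 108 and 476 with a robust fit, and 253 and 768 at an adjusted p below 0.10. In liver they were 15 and 9, then 1 and 2 with no trend, 0 and 0 in 1 fit over the 4 tissues with limma, and 25 and 27 at an adjusted p below 0.10. That fit gave 0 and 1 in brown fat and 1195 and 1230 in inguinal white fat, where the main counts were 0 and 0. It took 1 variance per gene over the 4 tissues, so it judged inguinal libraries against less variable ones and liver libraries against more variable ones. Without 1 library, higher genes ran from 0 to 472 in brown fat, 0 to 641 in epididymal white fat, 0 to 2384 in inguinal white fat and 21 to 175 in liver. Lower genes ran from 0 to 820, 0 to 480, 0 to 1719 and 29 to 279 in the same order.

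Lists called were 10 in brown fat, 11 in epididymal white fat, 11 in inguinal white fat and 13 in liver. An estimated correlation and fry each gave 0, 0, 0 and 0. Without 1 library they ran from 10 to 12, 13 to 15, 13 to 18 and 11 to 15.

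Genes whose effect differed numbered 461 between brown and epididymal white fat, 820 by separate fits and 80 to 714 without 1 library. Between brown and inguinal white fat there were 4, against 1 with quantile normalization, 7 by separate fits and 0 to 2424 without 1 library. For brown fat and liver the 0 became 23 by separate fits and 0 to 325 without 1 library. For both white fats the 0 became 1 with quantile normalization, 1 by separate fits and 0 to 3059 without 1 library. Epididymal white fat and liver gave 467, with 264 at a mean of at least 5 and 157 to 711 without 1 library. Inguinal white fat and liver gave 5, with 1 at a mean of at least 5, 3 with quantile normalization, 3 by separate fits and 0 to 3046 without 1 library. Genes lower in both epididymal white fat and liver were 1, then 3 at an adjusted p below 0.10 and 2 with median-centred libraries.

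Some sunitinib target kinases that did not pass turned direction without 1 library. These were Pdgfra in brown fat (−0.11 to 0.042), Flt4 (−0.083 to 0.45), Kit (−0.12 to 0.31), Kdr (−0.28 to 0.12), Pdgfra (−0.043 to 0.088) and Ret (−0.20 to 0.082) in epididymal white fat, Kdr (−0.12 to 0.10), Flt1 (−0.63 to 0.0041) and Flt3 (−0.53 to 1.73) in inguinal white fat, and Csf1r in liver (−0.29 to 0.013). Kdr in inguinal white fat was 0.024 with quantile normalization. The hepatocyte list in brown fat had medians from −0.26 to −0.012, and its test turned direction without vehicle replicate 2.

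The block and its check used the numbers of the description labels, because the titles number the sunitinib livers 3 and 4 and so share none with the vehicle livers. These numbers do not say that libraries of the same number share an animal, and with 2 pairs the correlation of their deviations, −0.256 in brown fat, 0.224 in epididymal white fat, 0.108 in inguinal white fat and 0.435 in liver, cannot settle it. With the number as a replicate block, genes higher and lower were 0 and 0 in brown fat, 254 and 424 in epididymal white fat, 0 and 0 in inguinal white fat and 287 and 470 in liver. Lists called were then 11, 13, 12 and 13 in the same order. The block gave 301 genes for the difference of brown and epididymal white fat, 0 for brown and inguinal white fat, 3 for brown fat and liver, 0 for both white fats, 903 for epididymal white fat and liver and 0 for inguinal white fat and liver. Pairing the brown fat numbers crosswise gave 0 and 0.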

Other observations

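The average over the fat depots, its genes and its test by other divisions of the libraries were chosen only after the result was seen. Its fit took libraries of different depots as independent, with 1 variance per gene. The labels do not say whether these libraries share mice. If they do, the p-values and gene counts of the average may overstate the evidence. Lep, which encodes leptin, fell in the average of the 3 fat depots by 1.19 ± 0.17 (adjusted p = 0.00668 in limma), with −1.21 in brown fat, −1.01 in epididymal white fat and −1.36 in inguinal white fat. In each depot both sunitinib libraries lay below both vehicle libraries, at 15.44 and 15.44 against 16.45 and 16.44 in epididymal white fat, 14.95 and 15.17 against 16.24 and 16.60 in inguinal white fat and 7.53 and 7.33 against 8.09 and 9.19 in brown fat, levels from separately normalized tables. C3ar1, a complement receptor of myeloid cells, fell by 0.77 ± 0.09 (adjusted p = 0.00423), with −0.13 in brown fat against −1.17 in epididymal and −1.002 in inguinal white fat. Paqr9, a membrane receptor family member, fell by 0.73 ± 0.06 (adjusted p = 0.00226), with −0.31, −0.85 and −1.02 in the same order. Lep, C3ar1 and Paqr9 kept their calls without each single library. None of them passed without the epididymal depot, where adjusted p in limma was 0.0768 for Lep, 0.103 for C3ar1 and 0.0580 for Paqr9. Cfd, Apoe and Gpx3 were followed in the same way and rose in the average. They were at 1.02 ± 0.21, 0.53 ± 0.10 and 0.71 ± 0.17 (adjusted p = 0.0239, 0.0181 and 0.0377 in limma). Each lost its call without several single libraries, without the brown fat depot and without the epididymal depot.

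In the average 307 genes rose and 809 fell, with 0 and 0 in limma without the epididymal depot, 74 and 537 without brown fat and 167 and 471 without the inguinal depot. The lower genes included some carried by 1 depot, such as Mss51, a gene of skeletal muscle, at 0.027 in brown fat, 0.028 in epididymal white fat and −2.77 in inguinal white fat, and Fabp3-ps1 at 0.19, 0.35 and −3.00. In the inguinal depot the skeletal muscle list had a median of −2.99, with −4.86 without sunitinib replicate 1 and −1.14 without sunitinib replicate 2. Higher and lower genes were 77 and 508 without brown fat vehicle replicate 1, 77 and 421 without vehicle replicate 2, 28 and 285 without sunitinib replicate 1 and 73 and 419 without sunitinib replicate 2. For epididymal white fat they were 55 and 362, 62 and 383, 82 and 385, and 117 and 440 in the same order of libraries, and for inguinal white fat 138 and 507, 107 and 499, 2116 and 1932, and 1218 and 1542. Of 100 divisions of the libraries drawn from 108, 1 gave as many genes, the real one with 1116, and the highest other gave 626. These divisions took each depot apart on its own, and the labels do not say whether libraries of different depots share mice. If they do, 3 divisions remain, too few for a share under 0.05.

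In epididymal white fat Atf3, a stress-induced transcription factor, fell by 1.42 ± 0.09 (adjusted p = 0.0121 in limma) and Plin2, a lipid droplet coat protein, by 1.01 ± 0.07 (adjusted p = 0.0175 in limma). Both calls were lost without vehicle replicate 1 or vehicle replicate 2. These genes were chosen after their values were seen.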
